A study of Mus musculus with 12 samples.

How the data were processed

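H3K9me3 and H3K27me3, histone marks found on silenced chromatin, were measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in female mouse cells of 2 kinds. EpiSCs are epiblast stem cells derived from embryos at day 6.5, and MEFs are embryonic fibroblasts from day 13.5. Cells were either wild type for Smchd1 (WT) or homozygous for the MD1 allele (MD1), which removes SmcHD1, a chromosomal protein of the SMC family needed to maintain X inactivation. All carried an Xist deletion on 1 X, so that the other X is the inactive one, in a cross between C57BL6/J and JF1 that lets reads be assigned to an allele. The 12 samples form 12 groups of 1 library, of which 8 are ChIP libraries and 4 are inputs.

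Per the labels' protocols, ChIP used mouse monoclonal antibodies and libraries were made with the NEBNext Ultra II kit. Per the submitters' processing notes, cutadapt, BWA and SAMtools were used with the mouse genome build mm9. The tool versions, the counting rule, any minimum coverage and any pseudocount are not given in the sources used here. The authors deposited log2 enrichment values for 952 X-linked genes, 1 value per gene and ChIP library. The deposited log2 values behave as ratios of whole numbers times 1 constant per library, read here as ChIP over the input of the same cells. What sets that constant, and which X the reads come from, is not given in the sources used here. Values are therefore reported as enrichment on the X as deposited, and every difference between libraries includes the ratio of 2 unknown constants.

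Whole-number pairs were recovered from the values. With 1 constant per library, 100% of the values in each library matched a ratio of whole numbers. The denominator was at most 30000 and the relative tolerance 1e-12. The 2 marks of the same cells were then given a common denominator by the procedure, so whether they share one was not tested. After the H3K9me3 values were moved by a small random amount, 0% matched, a control that was not run on H3K27me3. The pairs are the smallest that give each value, so the real read counts may be multiples of them and may include a pseudocount. Tested on simulated counts, the procedure recovered a pair for 100% of genes in each cell type and genotype, and the exact counts for 83.2% of 719 genes in the WT EpiSC simulation and 82.4% of 754 in the MD1 MEF simulation. The pairs were used only for 95% counting intervals of single-gene changes (normal approximation on the log scale). These intervals cover counting error only, not differences between cultures or preparations, and are approximate where a pair holds few counts.

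Coordinates are in mm9, counted from 1. The deposited starts count from 0: of 840 gene names matched in a RefSeq table of GRCm38.p6, 346 had the same length in both when starts were read that way and 36 when they were read as counting from 1. That table was used for nothing else. Genes had a value in 719 (WT EpiSC), 736 (MD1 EpiSC), 747 (WT MEF) and 754 (MD1 MEF) cases, always in both marks together. A value in all 8 libraries was present for 698 genes, while 184 had none. The median length was 20602 bases for the former and 1960 for the latter, so short genes are under-represented.

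Changes were computed as the MD1 minus the WT log2 value. A gene was counted as higher or lower at a change of at least 2-fold. H3K9me3-rich genes were those with at least 2-fold enrichment over input in WT cells. The original plan set that threshold as the inactive against the active X and spoke of windows. Because separate values for the inactive and the active X of a library were not used here, the threshold was set against input and genes took the place of windows. The planned comparisons of the inactive with the active X, and of autosomes with the X, were not run. Smchd1 is autosomal and was not analysed here, so the genotype labels were not checked against it. With 1 library per group no test across samples was possible within a cell type. A test of genotype with the cell types as 2 pairs would leave 1 residual degree of freedom and assume the same effect in both, and it was not run. No p-values across genes were computed, and no difference has a replicate check. Shares carry exact Clopper-Pearson intervals over genes, which describe these libraries and measure no spread between cultures. They take genes as independent, which neighbouring genes were not. Differences between rich and other genes, and correlations across genes, were set against 10000 random circular shifts of the gene order (707, 738 or 697 distinct shifts for 708, 739 or 698 genes). Lists were set against 10000 random lists of the same size, matched on mean enrichment of WT and MD1 for changes. That mean holds the change itself, so lists matched on the WT value alone were added after the results were seen. The 2 marks share an input, and the covariance this creates between their changes was simulated 200 times from the recovered pairs.

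The named genes, the lists and the settings below, unless said otherwise, were fixed before the data were examined. For each mark and cell type these were the 10 largest decreases and the 10 largest increases among genes whose higher value of the 2 lay above the median of that higher value over genes, and the 5 longest runs of adjacent H3K9me3-rich genes per cell type. Lists of genes escaping X inactivation, genes subject to it, landmark loci and gene clusters (Rhox, Xlr, Magea, Mageb, Ssxb, Slx, Nxf, Bex and Tceal) were used. Members of these clusters can share reads with near-identical copies, and their values are uncertain for that reason. A result for a member of the silenced list is not reported here, and it was left out of that list's values. The other settings tried were a pseudocount of 0.1, leaving out the lowest 10% of genes, means for medians, centring each library on its genes outside the H3K9me3-rich set, thresholds of 1.5-fold and 3-fold, the top 20% of genes, rich genes defined in the other cell type, runs of at least 3 rich genes, and Spearman's rho, exclusion of the most extreme 5% and averages over 5 neighbouring genes for correlations. The pseudocount was added to the fold enrichment over input, not to counts. Centring took from each library its median over the genes outside the rich set, so it removed any change those genes shared, real or not. Alternatives chosen after seeing the data were input pairs of at least 20, exclusion of the 137 genes that overlap another gene of the table, and genes with a value in all 8 libraries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.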

Results

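H3K9me3 and H3K27me3 enrichment was compared across X-linked genes between WT and SmcHD1-deficient MD1 cells at 2 developmental stages, to ask where each mark depends on SmcHD1. Each mark, genotype and cell type was measured in 1 library. Summed over genes, the smallest whole-number ChIP pairs came to 188886 (WT EpiSC), 33117 (MD1 EpiSC), 122980 (WT MEF) and 98736 (MD1 MEF) for H3K9me3, and to 1560574, 1804080, 879526 and 1186942 for H3K27me3 in the same order. The input pairs came to 182193, 181233, 237146 and 327173, with medians of 78, 85, 99 and 129.5 per gene. H3K9me3 in MD1 EpiSCs had the smallest ChIP pairs, with a median of 13 per gene, and changes of single genes there carry wide counting intervals.

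In WT EpiSCs, H3K9me3 covered most of the X-linked genes measured and lay in long blocks. Of 708 genes with values in both genotypes, 452 (63.8%) were H3K9me3-rich. The longest block ran over 95 consecutive measured genes from Chst7 to Igsf1 (X, 19636696 to 47150922) and took in the Rhox homeobox cluster, the ubiquitin-conjugating enzyme gene Ube2a and the cohesin subunit gene Stag2. Its median H3K9me3 value was 3.33 in WT and −1.27 in MD1. The next were a 70-gene block from Mycs to Gm14635 (X, 5044022 to 11932122), which holds the transcription factor genes Foxp3, Gata1 and Tfe3, a 53-gene block from P2ry10 to B230119M05Rik (104284674 to 131221001), a 46-gene block from Opn1mw to Tsga8 (71372805 to 82450389) and a 24-gene block from Cxx1a to Gpr101 (50945666 to 54756934). When the gene order was shuffled 1000 times, the longest run had a median of 13 genes and a maximum of 32. By position, among the 698 genes with all values, 100% of the 63 genes at 0 to 10 Mb, the 23 at 20 to 30 Mb and the 44 at 30 to 40 Mb were rich, against 22.9% of the 70 genes at 90 to 100 Mb, the interval that includes the ribosomal protein gene Rps4x.

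H3K27me3 was lower where H3K9me3 was high in WT EpiSCs. Its median was 3.48 in the rich genes and 4.70 in the other 256, and across genes the Pearson correlation of the 2 marks was −0.62, at the 0.16 percentile of circular shifts. Genes are not independent replicates.

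In MD1 EpiSCs, H3K9me3 was lower over nearly the whole set of X-linked genes. The median was 2.02 in WT and −1.27 in MD1, with a median change per gene of −2.98, a 7.92-fold lower enrichment, with lower values in 679 of the 708 genes (95.9%). It was at least 2-fold lower in 587 genes (82.9%, 95% interval 79.9 to 85.6) and at least 2-fold higher in 8 (2 without the lowest 10% of genes, 38 after centring). Of the 452 rich genes, 421 (93.1%, 95% interval 90.4 to 95.3) were under the 2-fold threshold in MD1. Their median change was −3.85, against −1.09 in the other genes. At least 2-fold lower were 444 of the rich genes (98.2%) as deposited and 407 after centring. The share under the threshold was not recomputed after centring. Rich genes chosen in WT MEF, and so not on the EpiSC value, were under the threshold in 85.2% of 135 cases.

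The 10 largest H3K9me3 decreases were at Cfp (properdin, a complement regulator), Praf2, Ube2a, Sat1 (a polyamine acetyltransferase), Rab9b, Nkrf, Was (the Wiskott-Aldrich syndrome protein), Rhox11, Rbm10 (an RNA-binding splicing factor) and Atp6ap1 (an accessory subunit of the proton pump). Their changes lay between −7.37 and −6.75. Was (X, 7658592 to 7667617) went from 4.44 to −2.44, a change of −6.88 (95% counting interval −8.44 to −5.33), and Rbm10 (20194629 to 20228031) from 3.61 to −3.15, a change of −6.76 (−8.22 to −5.30). Cfp (20502661 to 20508650) rested on an MD1 ChIP pair of 1, as did Praf2, Ube2a, Sat1, Rab9b, Rhox11 and Atp6ap1, and Nkrf rested on 2. The change of −7.37 at Cfp had an interval of −10.27 to −4.47. With a pseudocount of 0.1 Praf2 changed by −6.33, Was by −6.26, Cfp by −6.11 and Atp6ap1 by −5.04. The order of these decreases therefore depends on that setting. Among genes that met the naming rule none was higher as deposited: the 10 smallest decreases, at Samt4, Tsga8, Cdr1, Dcaf12l2, Gm16404, Gm6377, Gm773, 3830403N18Rik, Zfp300 and Pet2, lay between −1.47 and −0.20. Samt4 (150916545 to 150919225) had 2.82 in WT and 2.62 in MD1. After centring 5 of these 10 lay above 0: Samt4 (0.99), Tsga8 (0.62), Cdr1 (0.52), Dcaf12l2 (0.35) and Gm16404 (0.036).

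**Figure D1:**
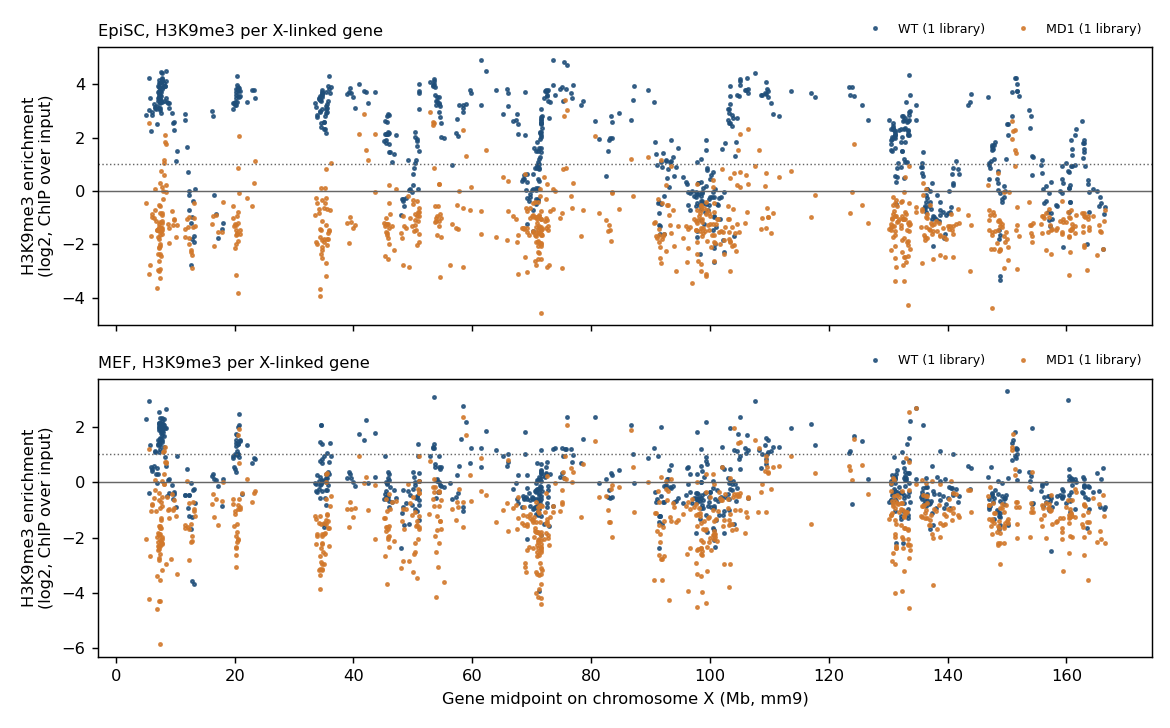
H3K9me3 enrichment (log2, ChIP over input) of each X-linked gene against its midpoint on the X (Mb, mm9) in EpiSCs and MEFs, 1 point per gene and 1 library per genotype, with the 2-fold threshold dotted. WT EpiSC values (median 2.03) form blocks above the threshold, and MD1 values lie around a median of −1.27.

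H3K27me3 did not follow a uniform shift in MD1 EpiSCs. Its median over the 708 genes was 4.19 in WT and 4.09 in MD1, with a median change of −0.069. Inside the H3K9me3-rich set the median change was 0.47, and outside it −0.48. The difference of 0.95 exceeded that of every circular shift (highest 0.93), and was 1.73 with rich genes defined in MEFs and 2.57 for the top 20% of genes. At least 2-fold higher H3K27me3 was found in 161 genes, of which 159 were rich, and at least 2-fold lower H3K27me3 in 80, of which 51 were not rich. Without the lowest 10% of genes 103 were higher, and 46 were lower after centring or 51 with input pairs of at least 20. Values in the 2 gene sets were 4.01 and 4.24 in MD1, closer than in WT.

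The 10 largest increases by the naming rule were at Rbm3 (a cold-inducible RNA-binding protein), Xlr, 4930453H23Rik, A230072C01Rik, Gm5124, Dkc1 (dyskerin, which modifies RNA and stabilises telomerase), Gm6938, Cdr1, Gm6890 and Gm15008. Rbm3 (X, 7716101 to 7723006) went from −0.11 to 4.44, a change of 4.54 (3.39 to 5.70), and Dkc1 (72341193 to 72355115) from 1.56 to 4.43, a change of 2.87 (2.10 to 3.64). For Gm6890 the interval of −0.40 to 5.46 included 0. The rule asked for a higher value above 4.36 and so left out larger increases, such as Tbc1d25 (4.88) and Brwd3 (4.25). In all, 61 genes were at least 8-fold higher. By the same rule the 10 largest decreases were at Rps4x, Ogt (O-GlcNAc transferase), Shroom2, Ercc6l, Ssr4, Rpl36a (a ribosomal protein), Trap1a, Slc7a3 (an amino acid transporter), Wbp5 and Cetn2. Rps4x (99380282 to 99383710) went from 5.61 to −0.33, a change of −5.95 (−7.24 to −4.66), and Ogt (98835390 to 98879690) from 4.56 to 0.45, a change of −4.11 (−4.45 to −3.77).

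Across genes, the changes of the 2 marks in EpiSCs had a Pearson correlation of −0.36 and a Spearman correlation of −0.46. Circular shifts gave correlations between −0.44 and 0.19, with the observed value at the 2.02 percentile. The covariance was −1.05, where the shared input alone gave 0.14.

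Centring each library on genes outside the rich set moved EpiSC changes by 1.19 for H3K9me3 and 0.47 for H3K27me3. The H3K9me3 median was then −1.80, with 452 genes lower and 38 higher, and the H3K27me3 median was 0.40, so its sign depends on the scaling. The mean H3K27me3 change as deposited was 0.35. Lower calls made up 33.2% of the 2-fold H3K27me3 calls as deposited and 17.0% after centring.

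**Figure D2:**
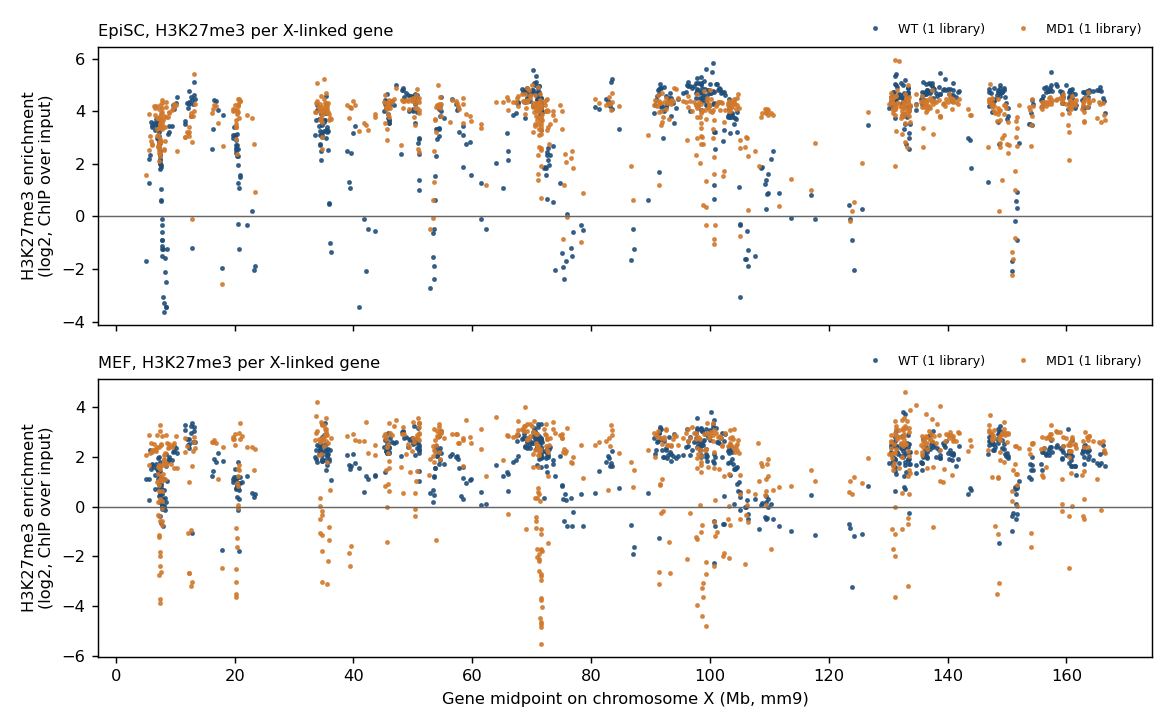
H3K27me3 enrichment (log2, ChIP over input) of each X-linked gene against its midpoint on the X (Mb, mm9) in EpiSCs and MEFs, 1 point per gene and 1 library per genotype. At least 2-fold higher in MD1 were 161 genes in EpiSCs and 165 in MEFs, and at least 2-fold lower were 80 and 177.

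In WT MEFs fewer genes were H3K9me3-rich at the same threshold over input. Library medians were also lower than in WT EpiSCs for both marks, −0.054 against 2.03 for H3K9me3 and 2.09 against 4.17 for H3K27me3. With an unknown constant per library, fewer marked genes cannot be told apart from another scale or a weaker ChIP in MEFs. Of 739 genes, 149 (20.2%) were rich, with a median of 1.52. The count was 68 at a 3-fold threshold, 89 with input pairs of at least 20 and 81 in runs of at least 3. The longest block held 41 genes from Foxp3 to Ssxb8 (X, 7156802 to 8267970), inside the 70-gene EpiSC block, and included Gata1, the histone deacetylase gene Hdac6 and Suv39h1, which encodes an H3K9 methyltransferase. Shuffled orders gave runs of at most 7. The next were Zfp711 to Gm382 (10 genes, 109714135 to 123598518) and 3 runs of 5 genes, Rbm10 to Araf (20194629 to 20437647), 3830403N18Rik to 6330419J24Rik (53389749 to 53631647) and Gm732 to Sh3bgrl (105141074 to 106357806). The Foxp3 to Ssxb8 block had a median of −1.88 in MD1, against 1.85 in WT, while Zfp711 to Gm382 had 0.40 against 1.26.

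In MD1 MEFs, H3K9me3 was lower by a median of −1.02, or 2.03-fold, and at least 2-fold lower in 379 genes (51.3%, 95% interval 47.6 to 54.9) against 5 higher (3 without the lowest 10% of genes). Of the 379, 264 were not H3K9me3-rich in WT. The median of all genes outside the rich set was −0.32 in WT and −1.31 in MD1. Of the 149 rich genes, 129 (86.6%, 95% interval 80.03 to 91.6) were under the threshold as deposited. That share was not recomputed after centring, which left 80 of the rich genes at least 2-fold lower in place of 115. The 10 largest decreases were at Slc35a2 (the UDP-galactose transporter), Tfe3, Pdzd11, Pcsk1n, B630019K06Rik, Pim2 (a kinase), Ebp (a sterol isomerase), Sowahd, Praf2 and Rpl10 (a ribosomal protein), between −7.42 and −4.86. Ebp (X, 7762457 to 7770638) had −3.17 in MD1, a change from WT of −5.13 (−6.50 to −3.75), and Slc35a2 (7461370 to 7471618) from 1.57 to −5.85 on an MD1 pair of 1, a change of −7.42 (−10.32 to −4.51). With a pseudocount of 0.1 Slc35a2 changed by −4.71 and Tfe3 by −4.88, so the order of the largest decreases depends on that setting. Pdzd11, Pcsk1n, B630019K06Rik, Pim2, Sowahd and Rpl10 also rested on an MD1 pair of 1. The 10 largest increases by the naming rule were at Cxx1a, H2bfm, 4921511C20Rik, Zcchc5, Kir3dl2, Gm14827, Serpina7, 4930524N10Rik, Ssx9 and 4933403O08Rik. They lay between 0.30 and 2.30, and all 10 counting intervals included 0. Centring moved all H3K9me3 changes in MEFs by 0.99 and left a median of −0.036, with 187 genes lower and 55 higher. Lower calls then made up 77.3% of the 2-fold calls in place of 98.7%. The set used for centring held 590 of the 739 genes, so a small median followed from the setting itself. A decrease shared by most MEF genes therefore cannot be told apart from the scaling.

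H3K27me3 in MD1 MEFs split the genes. It was at least 2-fold lower in 177 genes (24.0%, 95% interval 20.9 to 27.2), of which 173 had a counting interval that excluded 0 and 81 were at least 8-fold lower. It was at least 2-fold higher in 165 (22.3%), 153 of them beyond counting error. The median change was 0.34 and became 0.064 after centring, which moved all changes by −0.27, while the mean change was −0.23. Lower calls made up 51.8% of the 2-fold calls as deposited and 62.1% after centring.

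Among the 10 largest H3K27me3 decreases were those at Fam50a, Pdzd11, Lage3, Itgb1bp2, Huwe1 (a ubiquitin ligase), Usp9x (a deubiquitinase), Taf1 (a subunit of the general transcription factor TFIID), Zfx (a transcription factor) and Atp6ap1. Huwe1 (X, 148237825 to 148369961) went from 2.74 to −3.51, a change of −6.25 (−6.76 to −5.73). Usp9x (12648624 to 12750453) changed by −6.17 (−6.61 to −5.72), Taf1 (98728074 to 98797128) by −5.73 (−6.31 to −5.14) and Zfx (91319970 to 91368746) by −5.60 (−6.03 to −5.18). Fam50a (71558372 to 71565488) had the largest decrease, −8.87, on an MD1 pair of 1 (−11.85 to −5.88). Lage3 also rested on an MD1 pair of 1, and Pdzd11 on 2. A pseudocount of 0.1 gave −5.17 at Huwe1, −5.24 at Usp9x, −4.87 at Taf1 and −4.92 at Zfx, each outside its counting interval, and −6.39 at Fam50a. Added to the fold enrichment, it draws in values far under input whatever the counts. The MD1 ChIP pairs were 34 at Huwe1, 69 at Usp9x, 27 at Taf1 and 57 at Zfx. The 10 largest increases by the naming rule were at Fam47c, H2bfm, Zcchc5, Bex1, Slc38a5 (an amino acid transporter), Gm6890, Slitrk4, Ldoc1, Ngfrap1 and Gm6268, between 2.44 and 3.92. That rule left out Zfp300, which changed by 3.47. Slc38a5 (7848507 to 7857302) went from 0.08 to 2.85, a change of 2.76 (2.10 to 3.43).

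Genes rich in H3K9me3 in WT MEFs had a median H3K27me3 change of 0.998, against 0.28 in the other genes. The difference of 0.72 exceeded every circular shift (highest 0.61), and was 0.44 with rich genes defined in EpiSCs. Rich genes also had lower WT H3K27me3 (median 0.74, against 2.21), which the shifts do not hold equal. No match on that value was made in MEFs, so a larger rise at genes that start low is not excluded. The correlation of the 2 changes across genes was 0.34 (Spearman 0.28, Pearson 0.21 without the lowest 10% of genes), above the highest shift of 0.25, with a covariance of 0.87 where the shared input alone gave 0.12. Among 698 genes measured throughout, the 170 with lower H3K27me3 in MD1 MEFs had a median H3K9me3 change of −1.97, and the other 528 had −0.85.

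**Figure D3:**
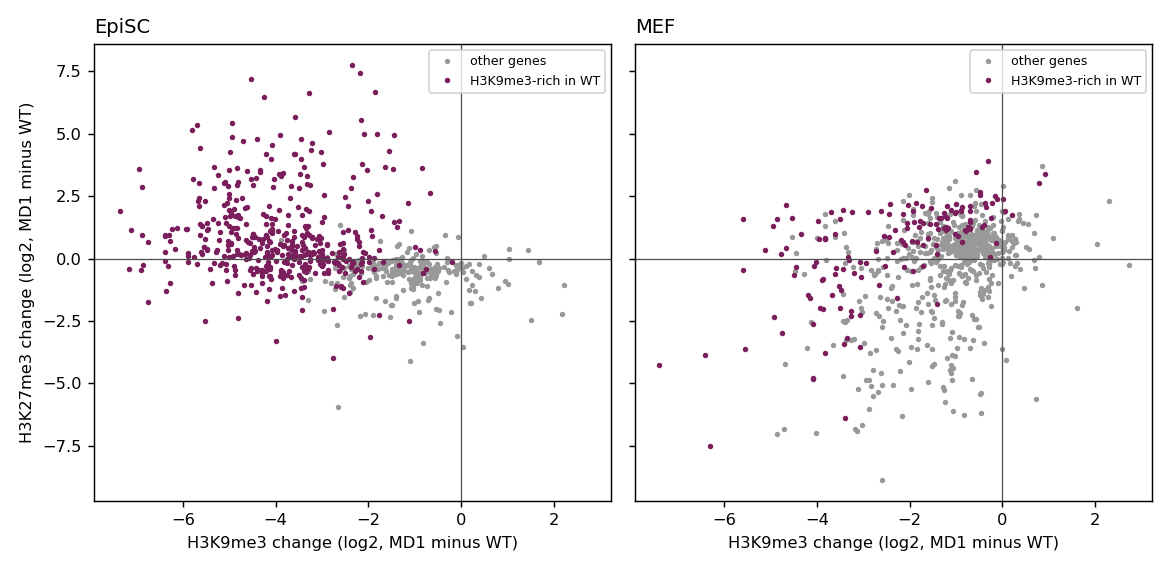
H3K27me3 change against H3K9me3 change (both log2, MD1 minus WT) for each gene in EpiSCs and MEFs, with genes H3K9me3-rich in WT of the same cell type marked. The Pearson correlation across genes was −0.36 in EpiSCs and 0.34 in MEFs.

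Genes known to be silenced on the inactive X had lower H3K27me3 in MD1 MEFs in every member analysed here. All 7 (Hprt, Pgk1, Atrx, G6pdx, Huwe1, Rlim and Gla) were at least 2-fold lower, as they were after centring, and their median went from 2.08 to −0.72. Changes ran from −1.90 at Gla to −6.25 at Huwe1. The median change of −2.74 lay at the 0.59 percentile of random lists matched on the WT value, and at the 12.7 percentile of lists matched on the mean of WT and MD1, which holds the change itself. In EpiSCs 0 of the 7 changed by 2-fold in H3K27me3 (1 after centring), with a median of −0.094 as deposited and 0.37 after centring. Huwe1 lay just under 2-fold at −0.99 (−1.26 to −0.73). Rlim (−0.76), Gla (−0.42) and G6pdx (−0.094) were also lower, and Hprt (0.57), Atrx (0.43) and Pgk1 (0.34) were higher. H3K9me3 in the same genes was at least 2-fold lower in 6 of 7 in EpiSCs (median −3.71) and in 5 of 7 in MEFs (median −2.14). These medians lay at the 11.6 and 2.6 percentiles of random lists matched on the WT value. After centring the medians were −2.53 and −1.15, with 6 and 4 genes lower. Pgk1, a glycolytic enzyme gene (X, 103382439 to 103399038), went from 3.56 to −1.92 in H3K9me3 in EpiSCs. This change of −5.49 (−8.47 to −2.50) rested on an MD1 ChIP pair of 1.

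Genes known to escape X inactivation had low medians of H3K9me3 and, in MEFs, of H3K27me3 already in WT, although Utp14a was H3K9me3-rich in WT EpiSCs (2.58). Their median WT H3K9me3 was −1.43 in EpiSCs and −1.22 in MEFs, at the 0.01 and 0.065 percentiles of random lists, and median WT H3K27me3 was 2.75 and −1.06. The histone demethylase genes Kdm6a and Kdm5c had WT H3K27me3 of −1.97 and 2.75 in EpiSCs and −1.76 and −1.45 in MEFs. In MD1 MEFs 5 of the 7 were at least 2-fold lower in H3K27me3, from −1.16 at Pbdc1 to −3.58 at Utp14a, while Kdm6a changed by −0.69 and Car5b had 2.24 in both. Of the 5, only Utp14a (2.15 in WT) had started above input, and the rest were lower from values already under it. The list's median change of −1.62 there lay at the 0.845 percentile of random lists matched on the WT value, and at the 58.7 percentile of lists matched on the mean. In MD1 EpiSCs 3 were lower in H3K27me3 (Kdm5c, Pbdc1 and Utp14a) and 1, Ddx3x, was higher. After centring Utp14a changed by −0.75 and 2 were lower. The Ddx3x change of 1.11 (0.037 to 2.19) was 0.96 with a pseudocount of 0.1, which is under 2-fold. It ran between values under input, −1.20 in WT and −0.090 in MD1. The list's median H3K9me3 changes were −0.45 in EpiSCs and −0.25 in MEFs, and became 0.73 and 0.74 after centring.

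**Figure D4:**
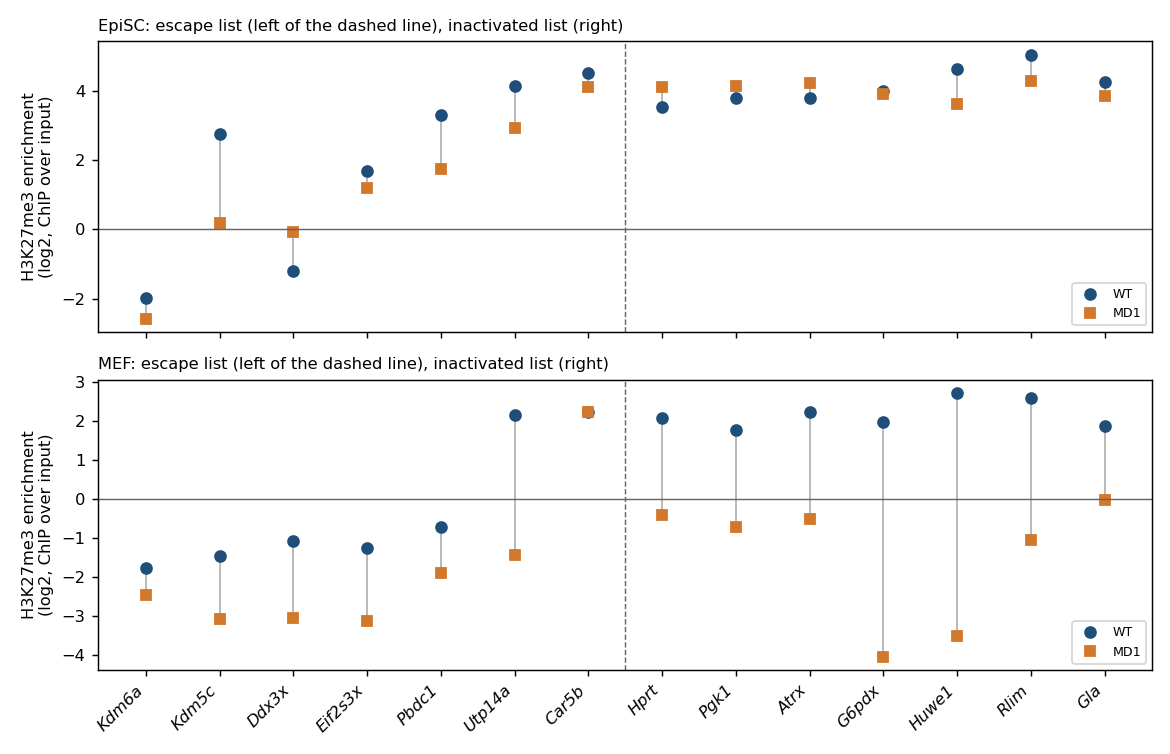
H3K27me3 enrichment (log2, ChIP over input) in WT and MD1 of 7 genes that escape X inactivation and 7 that are subject to it, in EpiSCs and MEFs, 1 library per point. In MEFs the 7 silenced genes lie between 1.79 and 2.74 in WT and between −4.03 (G6pdx) and −0.00 (Gla) in MD1.

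Xist, the RNA that starts X inactivation (X, 100655712 to 100678572), had H3K27me3 of 0.65 in WT EpiSCs and −1.04 in MD1, and −2.27 and −2.40 in MEFs. Firre (47908921 to 47988435) had 2.37 and 2.70 in EpiSCs and 2.04 and 1.61 in MEFs. The Dxz4 transcript 4933407K13Rik (72970797 to 73010038), at the hinge of the folded inactive X, had H3K9me3 of 2.75 in WT and −2.77 in MD1 EpiSCs, and −1.59 and −2.26 in MEFs. The median H3K9me3 change of these 3 loci was −0.94 in EpiSCs and −0.67 in MEFs, and became 0.25 and 0.32 after centring.

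The Ssxb cluster, a family expressed in testis, had high H3K9me3 without H3K27me3 in WT EpiSCs and high H3K27me3 in MD1 EpiSCs. In EpiSCs all 5 measured members had lower H3K9me3, with a median of 3.94 in WT and 1.17 in MD1, and higher H3K27me3, with medians of −3.07 and 3.68. After centring 4 of the 5 were at least 2-fold lower in H3K9me3. The H3K27me3 changes ran from 4.93 to 7.77, on WT ChIP pairs of 1 at Ssxb5 (interval 4.76 to 10.77) and Ssxb9 (3.49 to 9.47), 2 at Ssxb2, 3 at Ssxb8 and 11 at Ssxb10. The rule for named increases left these genes out, since the higher of each gene's 2 values, at most 4.34, lay under the median of that higher value over genes, 4.36. In MEFs 5 of 6 members had at least 2-fold higher H3K27me3 (median 1.43), and 3 of 6 after centring. That median lay at the 63.3 percentile of random lists matched on the WT value (random median 1.27), so it was near that of genes with similar WT values. The EpiSC median change in H3K27me3 lay at the 99.93 percentile. In the Rhox cluster 10 of 10 measured genes had lower H3K9me3 in MD1 EpiSCs (median −4.29), while H3K27me3 was at least 2-fold higher in 2 of 10, and in 6 after centring. All 10 were H3K9me3-rich in WT EpiSCs, and 98.2% of all rich genes were at least 2-fold lower. Against random lists matched on the WT value, the median H3K9me3 change lay at the 13.8 percentile and the H3K27me3 change at the 97.1 percentile. H3K9me3 was lower in 7 of 10 Rhox genes in MD1 MEFs, while after centring 3 were lower and 2 higher.

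The smaller clusters gave few values. Of all genes, 82.9% were at least 2-fold lower in H3K9me3 in EpiSCs and 51.3% in MEFs. Mageb had 3 of 3 genes lower in H3K9me3 and 2 of 3 higher in H3K27me3 in EpiSCs, and 2 of 3 higher in H3K27me3 in MEFs, where its H3K9me3 median was −0.89 and became 0.09 after centring. Among random lists matched on the WT value, its EpiSC changes lay at the 61.6 (H3K9me3) and 68.5 (H3K27me3) percentiles. The MEF H3K27me3 change lay at the 86.1 percentile. Magea had 2 genes measured in EpiSCs, with 1 lower in H3K9me3 (0 after centring) and 1 higher in H3K27me3, and 2 of 3 higher in H3K27me3 in MEFs. Tceal had 5 of 5 lower in H3K9me3 in EpiSCs and 3 of 4 in MEFs. Nxf had 3 of 3 lower in H3K9me3 in EpiSCs (2 after centring) and 0 of 3 in MEFs (1 higher after centring), where its median of −0.65 became 0.34 after centring. Its H3K27me3 median in EpiSCs was −0.23 and became 0.23. Bex1 had H3K27me3 of 1.78 in WT and 4.62 in MD1 MEFs, the other measured EpiSC member being Bex2. Xlr, the only member of its cluster with a change, had H3K27me3 changes of 3.502 in EpiSCs and 1.07 in MEFs, the latter 0.79 after centring. In MEFs its H3K9me3 change of −0.89 became 0.10 after centring. The Slx cluster had 0 measured genes.

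At the same threshold over input, H3K9me3-rich genes of MEFs were largely a subset of those of EpiSCs. The smaller size of the MEF list may come from the scale of those libraries. Of 698 genes with all values, 446 were rich in WT EpiSCs and 134 in WT MEFs, and 126 were shared (94.0% of the MEF genes) where independent lists would share 85.6 and circular shifts shared 57 to 127. At a 3-fold threshold 56 were shared, and 73 with input pairs of at least 20. In MD1, 32 and 18 genes were rich and 13 were shared, against 0.825 for independent lists. These 13, listed after their values were seen, were AU022751, Ssxb2, Ssx9, Zfp300, Cdr1, Ldoc1, Fam47c, Tsga8, Pet2, Gm732, 4930412D23Rik, 4930524N10Rik and Samt4. Across genes, EpiSC and MEF values correlated at 0.62 for WT H3K9me3, 0.74 for WT H3K27me3, 0.54 for MD1 H3K9me3 and 0.39 for MD1 H3K27me3, each above every circular shift. The changes correlated at 0.44 for H3K9me3 and 0.39 for H3K27me3, also above every shift.

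Lower H3K27me3 in MD1 was found in 77 genes in EpiSCs and 170 in MEFs, with 43 shared where independent lists would share 18.8. Higher H3K27me3 was found in 160 and 142, with 92 shared against 32.6. Between the cell types the difference in effect was not tested, since each has 1 library per genotype.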

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

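Of the tests in this part, the reads behind the MEF decreases and the match of H3K9me3-rich with other genes on WT H3K27me3 were chosen before their results were seen, and the other 6 were chosen after related values had been seen.

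H3K27me3 values in the 2 cell types had opposite signs at several points, and none of these differences was tested, since each cell type has 1 library per genotype. The median change was −0.069 in EpiSCs and 0.34 in MEFs, but the EpiSC interval over genes included 0 (−0.14 to 0.052), centring gave 0.40 and 0.064, and means gave 0.35 and −0.23. The correlation across genes of the H3K9me3 and H3K27me3 changes was −0.36 in EpiSCs and 0.34 in MEFs. H3K27me3 changed by 1.11 and −1.98 at Ddx3x, an RNA helicase gene that escapes X inactivation, in EpiSCs and MEFs. Its values lay under input throughout, at −1.20 in WT and −0.090 in MD1 EpiSCs, and −1.06 and −3.04 in MEFs. The changes were 0.57 and −2.47 at Hprt, 0.43 and −2.74 at Atrx, and 0.33 and −0.43 at Firre. Of the other silenced genes, Huwe1, Rlim, Gla and G6pdx were lower in both cell types.

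H3K9me3 was lower across the X in MD1 EpiSCs. A weaker or diluted ChIP would lower genes of equal WT value alike, yet 18 genes that were rich in MD1 MEFs had a median of 1.85 in MD1 EpiSCs and 79 genes matched on the WT EpiSC value had −1.05, a difference of 2.90 that exceeded the quartile range of the matched genes (1.46). A scaling factor would move every gene alike, yet genes rich in WT MEFs had a median change of −4.02 and others −2.63, a difference of −1.39. Both values argue against these explanations as the whole cause, while part of the median decrease may still come from scaling, since centring left −1.80. The genotype stays open and untested, since it cannot be separated from the library.

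H3K27me3 was lower at a subset of genes in MD1 MEFs, among them Huwe1 and the rest of the 7 silenced genes analysed. The shared input cancels in the H3K27me3 change minus the H3K9me3 change, and the list's median of that value lay at −3.03 relative to all genes, which argues against the input. A scaling factor would not leave 22.3% of genes at least 2-fold higher. Too few reads would leave intervals that include 0, but 97.7% of the 177 genes had one that excluded it. A biological difference of genotype is a candidate explanation that stays untested with 1 library per group, and which X gained or lost the mark is open.

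H3K27me3 was higher at H3K9me3-rich genes in MD1 EpiSCs. The shared input would give a positive covariance, and the observed one was −1.05. A narrower range of the MD1 library could raise low genes and lower high ones, and the match on WT H3K27me3 did not decide it: rich genes differed from matched genes by −0.023 (interval −0.31 to 0.22), but 76.6% of the matched genes were themselves rich in WT EpiSCs. A later test used the 9 genes with WT H3K27me3 of at most 2.91 that were not H3K9me3-rich, whose median change was −0.61 (interval −2.06 to 0.33), against 2.31 in the 168 rich genes in that range. This argues against a range that narrows by WT value alone, but those 9 are few and include Xist, Jpx, Firre and escape genes, so a narrower range and a genotype effect both stay open.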

How the results depend on the processing

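The alternatives with input pairs of at least 20, without overlapping genes, with genes in all 8 libraries and with random lists matched on the WT value were chosen after seeing the data, and the rest were planned. Of the values that answer a comparison, 115 stayed within their interval or, for counts, within 1.5 times, 39 moved further and 3 reversed. Of the single-gene values, 239 stayed within their counting interval and 53 left it, while 2 that were at least 2-fold as deposited changed sign. Alternatives that set the inactive against the active X could not be run, since separate values for each were not used here. No paired analysis was possible within a cell type because each group holds 1 library, and pairs across cell types were not tested. Unless a smaller gene set or the alternative's own construction shows it, the cause was not tested.

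Centring gave a median H3K9me3 change of −1.80 in EpiSCs and −0.036 in MEFs, and a median H3K27me3 change of 0.40 in EpiSCs (reversed) and 0.064 in MEFs. The centring set held most MEF genes, so the small MEF medians follow from the setting. Higher H3K9me3 was then counted in 38 EpiSC and 55 MEF genes, lower H3K9me3 in 187 MEF genes and lower H3K27me3 in 46 EpiSC genes. It changed the sign of 23 of 147 single-gene changes, 12 of them in EpiSC and 7 in MEF H3K9me3. Of these, 21 were under 2-fold as deposited, and the other 2 were Ddx3x and Gm16404, at H3K9me3 changes of 0.10 and 0.036 in EpiSCs. Means in place of medians reversed H3K27me3 to 0.35 in EpiSCs and −0.23 in MEFs, and gave −1.37 for H3K9me3 in MEFs. A pseudocount of 0.1 gave median H3K9me3 changes of −2.69 and −0.87, and 5 and 3 genes higher, in EpiSCs and MEFs.

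Without the lowest 10% of genes, the EpiSC median H3K9me3 change was −3.24, with 2 genes higher in EpiSCs and 3 in MEFs, H3K27me3 was higher in 103 EpiSC genes, rich and other genes differed by 0.75 in H3K27me3 change in EpiSCs, and the MEF correlation of changes was 0.21. With input pairs of at least 20, H3K9me3 was higher in 3 genes in each cell type, H3K27me3 was lower in 51 EpiSC genes, the MEF median H3K9me3 change was −0.93, 89 MEF genes were rich, 73 rich genes were shared, 95.9% of EpiSC rich genes were under the threshold, and the EpiSC correlation was −0.44. Without overlapping genes, 3 MEF genes had higher H3K9me3.

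The top 20% of genes gave 100% under the threshold and a rich minus other H3K27me3 difference of 2.57 in EpiSCs. Rich genes defined in the other cell type gave 85.2% and 1.73 in EpiSCs, and 96.0% and 0.44 in MEFs. The 96.0% does not measure loss. Of the 446 genes with all values that were rich in WT EpiSCs, only 126 were above the threshold in WT MEFs. A 3-fold threshold gave 68 rich MEF genes and 56 shared, and runs of at least 3 held 81 MEF genes. The EpiSC correlation was −0.46 as Spearman's rho, −0.43 without the most extreme 5% and −0.53 over averages of 5 neighbouring genes. Small counts limit single genes most in MD1 EpiSC H3K9me3, where the median ChIP pair was 13.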

Other observations

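In this part the test of gene length was chosen before its result was seen, and the tests of neighbouring genes and of which X is described, and the gene sets named, were chosen after related values had been seen.

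A set of 20 genes had at least 2-fold higher H3K27me3 in MD1 EpiSCs and at least 2-fold lower H3K27me3 in MD1 MEFs, where independent lists of 160 and 170 genes would share 39.0. They were Gripap1, Slc35a2, Suv39h1, Tbc1d25, Ddx3x, Usp11, Uxt, Ube2a, Lamp2, Cul4b, Mcts1, C1galt1c1, Thoc2, Xiap, Stag2, Fmr1, Vbp1, 2610002M06Rik, Brwd3 and Chm, and 19 of them were H3K9me3-rich in WT EpiSCs, as were 158 of the 160. Xiap, an inhibitor of apoptosis (X, 39421013 to 39462841), had H3K27me3 of 1.08 in WT and 4.15 in MD1 EpiSCs, and 1.53 and −2.37 in MEFs. Cul4b, a ubiquitin ligase scaffold (35884798 to 35929373), had 0.51 and 3.88 in EpiSCs and 1.94 and −0.82 in MEFs. Suv39h1 (7638297 to 7651886) had 0.62 and 2.86, and 0.81 and −2.61. Membership was uncertain at C1galt1c1, whose MEF decrease had a counting interval that included 0 (−3.23 to 0.063). It was also uncertain at Ddx3x, whose EpiSC increase was 0.96 with a pseudocount of 0.1 and whose H3K27me3 values lay under input in every library.

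The 13 genes H3K9me3-rich in both MD1 libraries had a median length of 2702 bases, and 13 of 13 were rich in WT EpiSCs. Their median H3K27me3 change was 2.31 in EpiSCs and 1.79 in MEFs. Fam47c had H3K9me3 of 4.73 in WT and 3.05 in MD1 EpiSCs, and 2.36 and 2.05 in MEFs.

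Genes with lower H3K27me3 in MD1 MEFs lay beside each other more than shuffled gene orders would place them. Both genes of 99 neighbouring pairs were at least 2-fold lower, against a median of 42 and a maximum of 62 in 10000 shuffles, and without overlapping genes 80 pairs were found against a maximum of 53. Neighbouring genes may therefore lose the mark together, as a hypothesis found and tested on the same libraries. By position, 34 of 72 genes at 70 to 80 Mb and 27 of 70 at 90 to 100 Mb were lower. In 100 of the 170 such genes with all values, H3K27me3 was at least 2-fold above input in WT and under it in MD1. Gene length did not set these genes apart: their median of 15716 bases lay within the 14760 to 23083 of random lists.

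The values may describe the inactive X, in which case genes that escape inactivation should carry little H3K27me3. The test asked for a WT median in the lowest 5% of random lists in both cell types, and it was met in MEFs (percentile 0.00) but missed in EpiSCs (percentile 6.12). In EpiSCs Utp14a and Car5b had 4.13 and 4.52. The list's WT H3K9me3 medians lay at the 0.01 and 0.065 percentiles in EpiSCs and MEFs. A miss this narrow with 7 genes does not exclude the inactive X, and which X the values describe stays open.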
